A study of Homo sapiens with 6 samples.

How the data were processed

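Poly(A) or total RNA selection is not given in the sources used here; per the labels, total RNA was taken with Trizol and a column kit from MHCC97H cells, and libraries were made with the EasyRNA-seq protocol. The labels divide the 6 libraries into 3 control and 3 resistant ones, numbered 1 to 3 in each group. The submitters' processing notes name Trimmomatic, HISAT2 and Bowtie2 without versions or roles. The read counter, the genome build, the annotation and the use of strand are not given in the sources used here, so overlapping and antisense genes, and near-identical family members, cannot be separated with certainty.

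The deposited values are whole-number counts per gene symbol for 19202 genes, not normalized, and the 6 columns of the table of the whole series equalled the counts of the single libraries. In the file 27 symbols had been turned into dates, and these were renamed from the Entrez ID. Totals ran from 1913469 to 5345272 counts per library. Among non-zero counts 63.6 to 69.1% were even, and among counts of 1 to 20 81.9 to 88.5%, a pattern that counting both mates of a pair would give. Counting errors based on these values would then be too small. The intervals given are bootstrap intervals of medians over genes, so they cover the spread between genes and not that between libraries. Replicates of a group differed by a chi-square per degree of freedom of 1.78 to 2.85 on halved counts, so none was taken for a repeat of another.

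Genes were filtered with filterByExpr (10804 tested), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with group as the only term. Adjusted p-values are Benjamini-Hochberg over the tested genes, with calls at 0.05. The SE of a log2 fold change is its size over the square root of F. The common dispersion was 0.017, a biological coefficient of variation of 13.0%. On data simulated for the 10804 genes of this comparison, 200 genes were changed. The test recovered 44.8% of genes changed 1.5-fold, 70.2% at 2-fold and 95.5% at 4-fold, with 4 false among 144 calls. The real comparison called 2601 genes, so its cutoff on the unadjusted p was looser. These shares are therefore not its own recovery.

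Before the data were examined, 38 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, and adjusted over the 34 lists. Camera with an estimated correlation and fry were alternatives. The genes named were PLEKHG5 and HDAC2; the 8 largest increases and 8 largest decreases among called genes with at least 5 CPM in the higher group and no overlap of libraries; of each list passing camera the 3 members with the smallest p in its direction; of each other list with at least 3 called members the 2 with the smallest p; and the most abundant marker of each other cell type. Other genes named, SNAI1, TGFBI, VIM, SPARC, RGS5, MT2A, NDUFB10, the histone genes and the genes seen in single libraries among them, were chosen after their values were seen. Some of the lists and genes that these rules take are not reported here.

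Other alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, 2 other filters, a replicate block, an adjusted p of 0.01 and leaving out each library. Halved counts, and leaving out control replicate 1 with resistant replicate 3, were added after the data were seen. Gene spans, transcript lengths and GC content were from GENCODE 29 (GRCh38), where 19143 of the symbols were found once. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.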

Results

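RNA sequencing was used to compare sorafenib-resistant MHCC97H cells with the sorafenib-sensitive control cells of the same line. MHCC97H is a human hepatocellular carcinoma cell line with high metastatic potential, and sorafenib is a multikinase inhibitor used against advanced liver cancer. There were 3 control and 3 resistant libraries. The deposited counts summed to 1913469, 5345272 and 3401241 in control replicates 1, 2 and 3, and to 3745068, 4280175 and 4961907 in resistant replicates 1, 2 and 3. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Levels are CPM, the counts scaled by library total and TMM factor, as mean ± SD with n = 3 per group, and log2 fold changes (log2FC) are resistant over control.

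The series title names PLEKHG5 and HDAC2, and the comparison addressed which transcripts differ between resistant and control cells. PLEKHG5 rose from 2.17 ± 1.37 CPM in control to 12.2 ± 3.44 CPM in resistant cells (SD, n = 3 each), 5.65-fold by the means. Its log2FC was 2.51 with a standard error (SE) of 0.48 and an adjusted p of 0.000123 in edgeR's quasi-likelihood test, and every resistant library lay above every control library. The level rested on few counts, 23 over the control and 157 over the resistant libraries. HDAC2, a class I histone deacetylase, differed much less, with 160 ± 22.9 CPM in control and 200 ± 17.6 CPM in resistant cells (SD, n = 3 each) and a log2FC of 0.31 (SE 0.11). The HDAC2 difference passed edgeR's quasi-likelihood test at an adjusted p of 0.034, but the groups overlapped. The call was lost in DESeq2 (adjusted p = 0.0551), and in edgeR without control replicate 1 (0.178), control replicate 2 (0.0727), resistant replicate 1 (0.068) or resistant replicate 3 (0.138). Over all alternatives the adjusted p of HDAC2 ranged from 0.0199 to 0.437. PLEKHG5 (Entrez 57449) lies on the minus strand of chromosome 1, from 6466092 to 6520061, and HDAC2 (Entrez 3066) on the minus strand of chromosome 6, from 113933028 to 114011308. These gene spans are from GENCODE 29 on GRCh38, matched by symbol, and the build behind the counts is not given in the sources used here.

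Across the transcriptome, 1269 genes were higher and 1332 lower in resistant cells among 10804 tested. At least 2-fold changes were fewer among the higher (175 genes) than among the lower genes (358 genes). In edgeR's quasi-likelihood test 3792 genes had an unadjusted p under 0.05, against 540.2 by chance. The first principal component of log2 CPM held 49.7% of the variance and separated the groups. Pearson correlations across genes were 0.956 to 0.972 within control, 0.970 to 0.973 within resistant and 0.919 to 0.954 between groups.

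The largest increases, with that of PLEKHG5, were in SLC14A1, MCAM, SPANXD, HLA-DPA1, ANKRD1, MAGEA12 and L1CAM. SLC14A1, a urea transporter, had 0.439 ± 0.761 CPM in control and 8.31 ± 0.247 CPM in resistant cells, with a log2FC of 3.69 (SE 0.68). The adhesion molecule MCAM rose from 6.94 ± 3.46 to 85.5 ± 11.0 CPM (log2FC 3.47, SE 0.22), and the neural adhesion molecule L1CAM from 6.80 ± 3.92 to 43.2 ± 14.6 CPM (log2FC 2.52, SE 0.28). ANKRD1, a YAP target, rose from 5.10 ± 3.55 to 38.3 ± 7.48 CPM (log2FC 2.72, SE 0.29). The class II antigen gene HLA-DPA1 had a log2FC of 3.02 (SE 0.60). The X-linked cancer-testis genes SPANXD and MAGEA12 had log2FC of 3.22 (SE 0.66) and 2.60 (SE 0.56), and are uncertain because near-identical family members can share their reads. The control counts behind the smallest of these levels were 7 for SLC14A1, 9 for SPANXD and 10 for HLA-DPA1. All 7 of SLC14A1 were in control replicate 2, so that control was at 0 without it, and limma-voom gave a log2FC of 4.49. Without control replicate 2 the log2FC was 4.08 for MCAM and 3.21 for L1CAM. Adjusted p in edgeR's quasi-likelihood test ranged from 5.37e-16 for MCAM to 0.000511 for MAGEA12.

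The largest decreases were in CLDN2, CEACAM5, CD99, SLC26A9, GCKR, CYP2B6, LRP2 and POU2AF1. CLDN2, a tight-junction claudin, fell from 18.8 ± 8.53 to 0.470 ± 0.814 CPM (log2FC -5.19, SE 0.63). The carcinoembryonic antigen gene CEACAM5 fell from 21.7 ± 3.04 to 0.906 ± 0.832 CPM (log2FC -4.51, SE 0.47), and the surface glycoprotein gene CD99 from 23.4 ± 8.16 to 0.951 ± 0.772 CPM (log2FC -4.51, SE 0.45). The drug-metabolising cytochrome CYP2B6 fell from 40.9 ± 1.09 to 3.31 ± 1.65 CPM (log2FC -3.62, SE 0.29). The log2FC was -3.91 (SE 0.64) for the anion transporter SLC26A9 and -3.69 (SE 0.67) for GCKR, the regulator of glucokinase. The endocytic receptor LRP2 had -3.46 (SE 0.81), and the B-cell coactivator POU2AF1 -3.43 (SE 0.53). Adjusted p in edgeR's quasi-likelihood test ranged from 1.35e-12 for CYP2B6 to 0.00138 for LRP2. The counts over the resistant libraries were 6 for CLDN2, 6 for LRP2 and 8 for GCKR, so these sizes rest on few counts. All 6 of CLDN2 were in resistant replicate 2, and its log2FC was -4.53 without resistant replicate 3. Without resistant replicate 3 the log2FC was -5.33 for CEACAM5, -5.44 for CD99 and -3.05 for GCKR, and without resistant replicate 2 it was -4.98 for GCKR and -4.39 for LRP2. LRP2 had -2.86 without control replicate 1, and limma-voom gave -5.14 for CEACAM5.

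**Figure D1:**
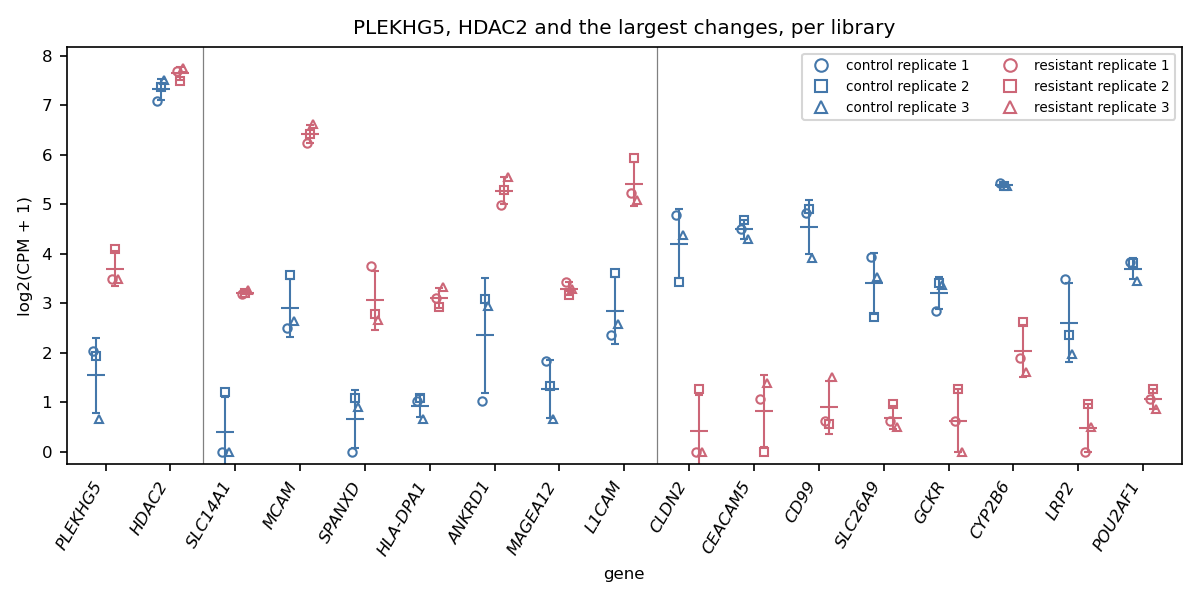
Levels of PLEKHG5, HDAC2 and the genes with the largest changes, as log2(CPM + 1) on the vertical axis; each symbol is 1 library, horizontal dashes are group means and bars are SD on that scale (n = 3). The 3 resistant libraries lie apart from the 3 control libraries for every gene except HDAC2.

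In gene span on GRCh38, SLC14A1 lies on chromosome 18 from 45687025 to 45752520, MCAM on chromosome 11 from 119308529 to 119321521, and ANKRD1 on chromosome 10 from 90912096 to 90921276. L1CAM, SPANXD and MAGEA12 lie on chromosome X, at 153861514 to 153886174, 141697411 to 141698739 and 152733779 to 152737669. HLA-DPA1 is on chromosome 6 from 33064569 to 33080775. CLDN2 is on chromosome X from 106900164 to 106930861, CEACAM5 on chromosome 19 from 41708585 to 41729798, and CYP2B6 on the same chromosome from 40991250 to 41018398. SLC26A9 is on chromosome 1 from 205913048 to 205943460, GCKR on chromosome 2 from 27496842 to 27523684, LRP2 on chromosome 2 from 169127109 to 169362685, and POU2AF1 on chromosome 11 from 111352252 to 111455630. CD99 was not placed, because its symbol was not found exactly once in the annotation.

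Of 38 gene lists fixed before the data were examined, 34 had at least 5 tested genes. Of these, 6 passed limma's camera test with a preset correlation of 0.01, and "as a list" below means only that. In the same test, control replicates 1 and 2 with resistant replicate 2 against the other libraries passed 5 lists, with 0 genes called. None of the 6 lists passed camera with an estimated correlation, where the lowest adjusted p over the 34 lists was 0.469. The estimated correlation was -0.007 for NF-kappaB targets and -0.039 for hepatocyte genes, below the preset. Their unadjusted camera p still rose, from 0.000465 to 0.0191 and from 0.00158 to 0.0276. A lost pass in that setting therefore does not by itself show correlated members. Counts of called members are over all genes tested, and the count adjusted over the list alone is given where it differed. Of all tested genes 24.1% were called, so a list with a share near this does not stand out by its count. Median and mean log2FC differed in sign for the fatty acid oxidation (mean -0.24), hypoxia and glycolysis (-0.04), TGF-beta (-0.01), nuclear oxidative phosphorylation (-0.01), replication-dependent histone (-0.08) and endothelial (-0.03) lists, whose medians were 0.00 to 0.07. The epithelial list had a median of -0.00267 and a mean of -0.16 with camera's direction up, and the interferon list was up in camera and down in fry.

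Ribosomal protein genes rose as a list: 29 of 57 were higher and 1 lower (37 and 1 adjusted over the list alone), with a median log2FC of 0.27 and a camera adjusted p of 2.91e-06 (adjusted p = 0.75 with an estimated correlation). RPS16 (log2FC 0.58, SE 0.09), RPL23 (0.59, SE 0.09) and RPS24 (0.53, SE 0.09) had the smallest p. The list's mean log2 CPM lay higher in each resistant library than in each control library by at least 0.074, while the resistant libraries spanned 0.305.

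Genes of G2/M and mitosis fell as a list: 16 of 36 were lower and 1 higher (18 and 1 adjusted over the list alone), with a median log2FC of -0.29 and a camera adjusted p of 0.0013 (adjusted p = 0.70 with an estimated correlation). The DNA topoisomerase TOP2A fell from 371 ± 53.8 to 198 ± 5.82 CPM, the kinetochore protein CENPF from 406 ± 12.9 to 266 ± 20.99 CPM, and the proliferation marker MKI67 from 394 ± 32.1 to 257 ± 39.7 CPM. Of the G1/S and DNA replication genes, 7 of 36 were lower and 3 higher (7 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.355). The replication factor CDC45 (log2FC -1.49, SE 0.29) and E2F1 (-1.03, SE 0.22) were lower.

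Target genes of NF-kappaB fell as a list: 6 of 19 were lower and 1 higher (8 and 1 adjusted over the list alone), with a median log2FC of -0.37 and a camera adjusted p of 0.00528 (adjusted p = 0.469 with an estimated correlation). The chemokine CXCL2 fell from 46.8 ± 3.03 to 14.4 ± 0.672 CPM, the cytokine CSF1 from 223 ± 16.3 to 125 ± 7.45 CPM, and the adhesion molecule ICAM1 from 124 ± 3.16 to 69.9 ± 12.7 CPM.

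Hepatocyte genes fell as a list with 3 of 16 called lower and 0 higher, a median log2FC of -0.60 and a camera adjusted p of 0.0134 (adjusted p = 0.469 with an estimated correlation). The apolipoprotein APOB fell from 23.2 ± 5.79 to 8.08 ± 5.01 CPM and albumin, ALB, from 17.3 ± 3.75 to 5.53 ± 3.502 CPM. SERPINA1 had a log2FC of -1.44 (SE 0.49, adjusted p = 0.0268 in edgeR), and lost the call in DESeq2 (0.0509) and in edgeR without control replicate 2 (0.11), control replicate 3 (0.0902), resistant replicate 2 (0.114) or resistant replicate 3 (0.0543).

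Cholesterol synthesis genes and their regulators fell as a list: 7 of 23 were lower and 0 higher (8 and 0 adjusted over the list alone), with a median log2FC of -0.36 and a camera adjusted p of 0.0282 (adjusted p = 0.70 with an estimated correlation, and 0.0956 in camera without control replicate 1). DHCR7, an enzyme of the last steps of synthesis, fell from 52.5 ± 2.504 to 28.5 ± 2.26 CPM, and the transcription factor SREBF2 from 98.8 ± 1.85 to 63.9 ± 4.43 CPM. Among fatty acid synthesis and desaturation genes, 7 of 19 were lower and 3 higher (7 and 4 adjusted over the list alone; camera adjusted p = 0.549), with the desaturase FADS2 at a log2FC of -1.20 and the elongase ELOVL1 at 0.59. Among fatty acid oxidation genes, 3 of 24 were lower and 2 higher (camera adjusted p = 0.549), with the lipid droplet protein PLIN2 at 0.63 and the dehydrogenase HADH at -0.79.

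ABC drug transporters fell as a list: 7 of 12 were lower and 0 higher, with a median log2FC of -0.34 and a camera adjusted p of 0.0282. The adjusted p was 0.70 with an estimated correlation, and 0.0956 and 0.0621 in camera without control replicate 1 and control replicate 2. The cholesterol exporter ABCA1 fell from 245 ± 19.8 to 102 ± 16.7 CPM, and ABCA2, also a lipid transporter, from 79.0 ± 11.8 to 35.7 ± 4.37 CPM. The multidrug efflux pump ABCB1 fell from 51.6 ± 17.2 to 30.0 ± 1.62 CPM. Its level in control replicate 1, 31.9 CPM, was close to the 28.2 to 31.0 CPM of the resistant libraries. Control replicates 2 and 3 had 63.8 and 59.0 CPM. Of the xenobiotic metabolism enzymes, 7 of 18 were lower and 4 higher (8 and 4 adjusted over the list alone; camera adjusted p = 0.101), and the aldehyde dehydrogenase ALDH3A1 fell from 613 ± 116 to 155 ± 32.6 CPM. Of the NRF2 targets, 7 of 25 were lower and 4 higher (camera adjusted p = 0.387), with the glutathione peroxidase GPX2 at a log2FC of -2.24 and OSGIN1 at -0.90.

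**Figure D2:**
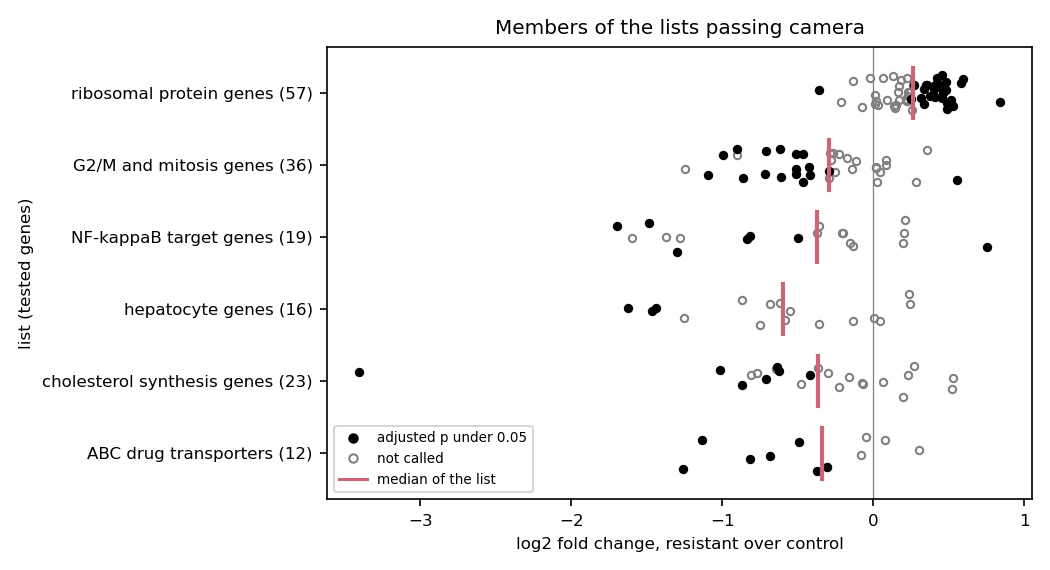
Log2 fold change, resistant over control, of each tested member of the 6 lists that passed camera; filled points were called at an adjusted p under 0.05 in edgeR, open points were not, and the vertical bar is the list median. Medians lie at 0.27 for ribosomal protein genes and between -0.60 and -0.29 for the other lists.

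Among sorafenib target kinases and other receptor kinases, 2 of 14 were higher and 6 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.355). The receptor kinase AXL rose from 152 ± 11.7 to 450 ± 21.5 CPM (log2FC 1.57, SE 0.10), and ERBB3 fell from 56.7 ± 0.744 to 17.9 ± 0.509 CPM (log2FC -1.66, SE 0.18). ERK output genes were 3 higher and 4 lower of 19 (camera adjusted p = 0.875), with cyclin D1, CCND1, at 0.88 and the ephrin receptor EPHA2 at 0.49. The YAP and TAZ targets were 5 higher and 1 lower of 22 (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.0638. That list passed camera without resistant replicate 1 (0.0159), without a filter on low counts (0.0192) and with a minimum of 1 CPM in 3 libraries (0.0494). It did not pass with an estimated correlation (adjusted p = 0.70 with an estimated correlation) or in fry (adjusted p = 0.0549). Of the Wnt and beta-catenin targets, 4 of 13 were higher and 2 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.873). The Wnt inhibitor DKK1 rose from 77.7 ± 11.7 to 327 ± 46.7 CPM, and the metalloproteinase MMP7 fell from 185 ± 16.0 to 65.1 ± 13.1 CPM. The TGF-beta targets divided evenly, 4 higher and 4 lower of 22 (camera adjusted p = 0.875), with BAMBI at -0.63 and TGIF1 at -0.59.

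Histone deacetylases and sirtuins were 2 higher and 2 lower of 16 (camera adjusted p = 0.875). HDAC9 rose from 73.8 ± 17.7 to 128 ± 8.62 CPM, and SIRT2 had a log2FC of -0.62 that lost its call without control replicate 1 (adjusted p = 0.109 in edgeR) or resistant replicate 1 (0.0874). Of the histone acetyltransferases, 5 of 14 were lower and 1 higher (camera adjusted p = 0.153). NCOA3 had a log2FC of -0.46 and EP300 of -0.33, and the EP300 call was lost without control replicate 2 (adjusted p = 0.0567 in edgeR).

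Stress and death genes moved in both directions. In fry the ATF4 (adjusted p = 0.0448), BCL2 family (0.0294) and autophagy (0.0444) lists passed with the direction down. The ATF4 and amino acid stress genes were 4 higher and 7 lower of 25 (6 and 10 adjusted over the list alone; camera adjusted p = 0.355), with ATF3 at a log2FC of -1.29 and DDIT3 at -1.31. The unfolded protein response chaperones were 2 higher and 4 lower of 20 (camera adjusted p = 0.468), with PDIA4 at -0.78 and XBP1 at 0.53. The p53 targets were 3 higher and 5 lower of 22 (camera adjusted p = 0.597), with SESN2 at -0.99 and the death receptor TNFRSF10B at -0.71. Of the BCL2 family and inhibitors of apoptosis, 1 of 20 was higher and 5 lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.347), with the survival genes MCL1 and BIRC5 both at -0.71. MCL1 lies on chromosome 1 between 116910057 and 151538692, where 32 of 93 tested genes were lower. The ferroptosis regulators were 4 higher and 6 lower of 22 (camera adjusted p = 0.656), with the iron exporter SLC40A1 at -1.60 and the mitochondrial channel VDAC2 at 1.12. Of the autophagy and lysosome genes, 2 of 38 were higher and 10 lower (camera adjusted p = 0.177), and the protease CTSL fell from 1043 ± 43.2 to 414 ± 39.4 CPM and the kinase ULK1 from 209 ± 14.4 to 84.2 ± 2.27 CPM. Of the metallothioneins, 1 was tested, MT2A, and it was called higher (log2FC 1.63, SE 0.52), although the groups overlapped. Its call was lost without control replicate 1 (adjusted p = 0.0753 in edgeR), control replicate 2 (0.146) or resistant replicate 3 (0.254), and its log2FC was 2.94 without control replicate 3.

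Epithelial genes were 4 higher and 3 lower of 19 (5 and 4 adjusted over the list alone; camera adjusted p = 0.875), with the claudins CLDN4 at 0.95 and CLDN1 at 0.54. Mesenchymal genes were 4 higher and 2 lower of 18 (camera adjusted p = 0.609). Fibronectin, FN1, fell from 12866 ± 694 to 7450 ± 1303 CPM and S100A4 from 716 ± 45.0 to 506 ± 45.7 CPM. The genes called higher were SNAI1 (log2FC 0.98), TGFBI (0.40), VIM and SPARC. For SNAI1 and TGFBI every resistant library lay above every control library, while VIM and SPARC were highest in resistant replicate 3. VIM had 55.6 CPM in that library, 24.9 and 11.8 CPM in resistant replicates 1 and 2, and 13.7 to 14.7 CPM in control. SPARC had 44.6 CPM in resistant replicate 3 and 2.71 and 4.23 CPM in the other resistant libraries. Without resistant replicate 3 the log2FC was 0.36 for VIM (adjusted p = 0.471 in edgeR) and -0.30 for SPARC (0.814), and SPARC also lost its call without control replicate 2 (0.0951). Of the liver cancer stem cell markers, 0 were higher and 3 of 13 lower (camera adjusted p = 0.177), among them ICAM1 and the efflux pump ABCG2 (log2FC -0.49).

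Of the mitochondrially encoded genes, 6 of 13 were lower and 0 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.181), with MT-ND2 at -0.31 and MT-ND6 at -0.34. These genes held 7.84 to 8.14% of counts in control and 6.86 to 7.35% in resistant libraries. Of the nuclear oxidative phosphorylation genes, 1 of 32 was lower and 0 higher (camera adjusted p = 0.903), and it was NDUFB10 (log2FC -0.54), which lost its call without control replicate 1 (adjusted p = 0.0987 in edgeR) or resistant replicate 2 (0.0515). The hypoxia and glycolysis genes were 3 higher and 3 lower of 25 (camera adjusted p = 0.875), with NDRG1 at -1.01 and the enolase ENO2 at 1.19. The replication-dependent histone genes were 1 higher and 1 lower of 13 (camera adjusted p = 0.875), HIST1H4C at 0.38 and HIST1H1E at -0.76.

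Few markers of other cell types were tested or called. Of 14 endothelial markers, 3 were tested and 0 called, and ESAM, the most abundant, had 70.6 ± 0.571 CPM in control and 74.3 ± 11.4 CPM in resistant cells. Of 18 leukocyte markers, 4 were tested and 0 called, and CD79A had 9.71 ± 1.24 and 6.65 ± 1.28 CPM. Of 15 fibroblast and stellate cell markers, 4 were tested, 1 was higher (RGS5, log2FC 1.53) and 1 lower (COL6A3, -0.85), or 1 and 2 adjusted over the list alone. RGS5 had 19.2 CPM in resistant replicate 3 against 7.58 and 7.05 CPM in the other resistant libraries, and its call was lost without that library (log2FC 0.90, adjusted p = 0.271 in edgeR). In resistant replicate 3, however, VWF reached 26.2 CPM, CDH5 19.2 CPM and MMRN1 22.3 CPM, against at most 1.76, 3.09 and 1.17 CPM in any other library. The interferon-stimulated genes were 3 higher and 1 lower of 19 (camera adjusted p = 0.988). The IFIT3 and IFI27 calls rested on resistant replicate 3, with adjusted p of 0.545 and 0.702 in edgeR without it. IFI27 also lost its call in DESeq2 (0.319), and IFIT3 and IFI27 lost theirs in limma-voom (0.0686 and 0.082).

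**Figure D3:**
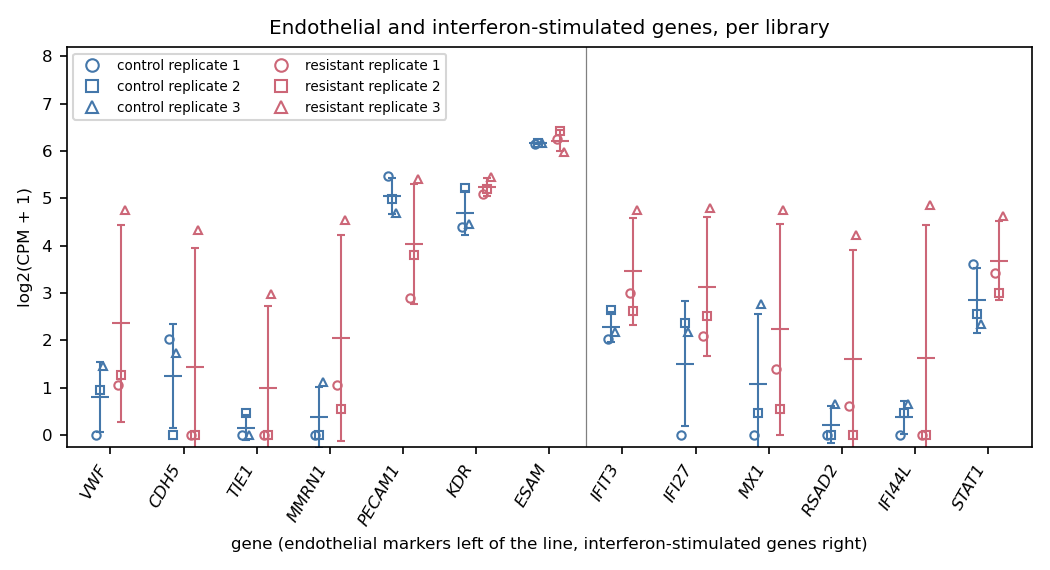
Endothelial markers and interferon-stimulated genes as log2(CPM + 1) per library, chosen after their values were seen; symbols are libraries, dashes are group means and bars are SD on that scale (n = 3). VWF, CDH5, TIE1, MMRN1, MX1, RSAD2 and IFI44L stand higher in resistant replicate 3 than in the other 5 libraries.

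Chromosome 10 stood apart from the other autosomes and X: its 418 tested genes had a median log2FC of 0.30, with 129 called higher and 12 lower. Chromosome Y, with 6 tested genes, had a median of -1.28, with 5 called lower. The medians of the other autosomes and X lay between -0.074 and 0.033. ANKRD1, DKK1, VDAC2, IFIT3, RPS24, MKI67 and BAMBI are on chromosome 10, and the last 2 were lower.

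**Figure D4:**
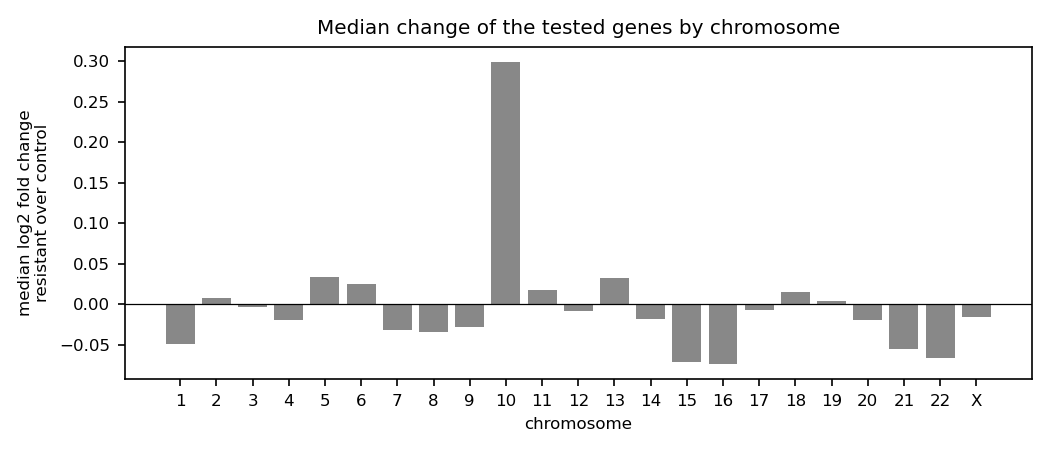
Median log2 fold change, resistant over control, of the tested genes on each of chromosomes 1 to 22 and X. The bar of chromosome 10 reaches 0.30, and the others lie between -0.074 and 0.033.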

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

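Halved counts, and leaving out control replicate 1 with resistant replicate 3, were chosen after seeing the data. The PLEKHG5 increase kept its direction and call in all 16 alternatives (log2FC 2.07 to 2.93, adjusted p 1.43e-06 to 0.00521 over edgeR, DESeq2 and limma-voom), and 2.07 to 2.93 is also its range when each library was left out. HDAC2 kept its direction but lost its call in DESeq2 (log2FC 0.32, adjusted p = 0.0551), in edgeR without control replicate 1 and resistant replicate 3 together (0.17, adjusted p = 0.437), and in 4 of the 6 fits without 1 library (0.22 to 0.41 over the 6). The adjusted p of HDAC2 was 0.178 without control replicate 1 and 0.138 without resistant replicate 3; fewer samples entered these fits, and the cause was not tested further. Leaving out 1 library gave 1028 to 1107 higher and 973 to 1154 lower genes, 165 to 217 at least doubled and 309 to 377 at least halved, and 4 to 7 lists passing camera. At an adjusted p of 0.01 there were 800 higher and 851 lower genes, by construction fewer. Of the 6 lists passing camera, 0 passed with an estimated correlation, and 4 passed fry, which asks another question; ribosomal protein genes (adjusted p = 0.092) and ABC drug transporters (0.0549) did not. In all, 12 lists passed fry. Those that passed fry but not camera in the main fit all had the direction down. Among them were xenobiotic metabolism enzymes (fry adjusted p = 0.0091) and the BCL2 family and inhibitors of apoptosis (0.0294). The autophagy and ATF4 lists had 0.0444 and 0.0448. The mitochondrially encoded, receptor kinase and fatty acid synthesis lists each had 0.0495. Xenobiotic metabolism enzymes also passed camera on halved counts (adjusted p = 0.0378). Lists were not tested with DESeq2 or limma-voom. Without control replicate 1 and resistant replicate 3, 848 genes were higher and 910 lower, and 4 lists passed. No gene was called in opposite directions in any alternative. Library-total scaling gave 45.1% of calls higher, against 48.8%. Of 86 named genes, 84 were called, of which 75 kept direction and call in every alternative and 9 lost the call in at least 1. LRP2, HADH and CLDN1 lost it only without those 2 libraries together (adjusted p = 0.055, 0.0526 and 0.0573 in edgeR). Most of these genes were named for large changes or small p in these data, which favours keeping the call. Over all genes, the fit without control replicate 3 kept 970 of the 1269 higher and 926 of the 1332 lower calls. The replicate numbers did not pair the libraries: deviations from the group means correlated at -0.015, 0.033 and -0.006 across genes, and 1 of the 3 control libraries had its best partner in its own number. With the replicate block there were 1248 higher and 1270 lower genes, and 6 lists passed camera; in fry with the block 1 list passed, hepatocyte genes (adjusted p = 0.0368). The single files equalled the table, so that alternative gave no value. At this depth, spread and number of libraries, and with 200 genes changed, the simulation recovered 44.8% of genes changed 1.5-fold. The shares of depth, spread and number of libraries in the loss were not separated. The real comparison called 2601 genes and so had a looser cutoff on the unadjusted p, and its own recovery was not simulated.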

Other observations

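The lists in this paragraph were chosen after the data were seen. A list of HLA class II genes, CD74 and transcriptional regulators of these genes was 4 higher and 1 lower of 8 tested. HLA-DPA1 (log2FC 3.02), HLA-DRA (1.24), CD74 (1.57) and the regulator RFXAP (1.83) were higher, and the regulator RFX5 (-0.45) was lower. HLA-DMA had -0.68, RFXANK 0.27 and the activator CIITA 0.12 (edgeR adjusted p = 0.472, 0.591 and 0.903). For HLA-DRA the groups overlapped, with 12.6 CPM in control replicate 2 and 11.5 CPM in resistant replicate 2. Without control replicate 2 the log2FC was 2.20 for CD74 and 2.33 for HLA-DRA. The HLA-DRA call was lost in edgeR without control replicate 1 (adjusted p = 0.0639), control replicate 3 (0.093) or resistant replicate 1 (0.0536). The RFXAP call was lost without any 1 library (0.0527 to 0.189), and that of RFX5 without any 1 except control replicate 1 (0.0521 to 0.192). Of 9 tested cancer-testis genes on X, 5 were higher, SPANXB1 (2.37), SPANXC (1.30), SPANXD (3.22), MAGEA12 (2.60) and MAGEC2 (1.34), and MAGEA6 was lower (-1.39); reads shared between near-identical members leave these values uncertain. The edgeR call was lost for SPANXC without control replicate 1 (adjusted p = 0.0928), control replicate 2 (0.0673) or resistant replicate 1 (0.214), and for MAGEA6 without any 1 library except resistant replicate 1 (0.0606 to 0.127). Heat shock chaperones were 9 higher and 2 lower of 21. HSPA8 lay at 321 to 357 CPM in control and 865 to 1000 CPM in resistant libraries (edgeR adjusted p = 3.8e-16) and DNAJA1 had 1.04, while HSPB1 (-0.50) and CACYBP (-0.73) were lower. Tubulin genes were 5 higher and 0 lower of 10, led by TUBB2B (2.27) and TUBA4A (0.78).

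Neighbouring genes changed together on chromosomes 1 and 10; the test on isolated genes was chosen after the first results were seen, the others before. Windows of 50 tested genes passed every one of 1000 shuffles of gene order in 4 segments: chromosome 10 from 3137728 to 27155266 (median log2FC 0.37) and from 60026298 to 92291087 (0.39), and chromosome 1 from 116910057 to 151538692 (-0.46) and from 154983338 to 160098943 (-0.42). Reads shared between adjacent genes were not excluded genome-wide by the test set beforehand, since the correlation between genes 10 apart, 0.022, lay within the shuffled range (highest 0.028, with 13 of 1000 shuffles as high). Within the 4 segments, genes with no other gene within 10 kb still had medians of 0.281, 0.344, -0.461 and -0.597 (bootstrap intervals nearest 0 at 0.118, 0.172, -0.212 and -0.13, the last from 6 genes), which argues against shared reads there, though the segments had been picked for their shift. A copy number or other regional difference between the 2 cell populations may account for these 4 segments; DNA was not analysed here, and regional regulation was not tested.

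Resistant replicate 3 had endothelial and interferon genes at higher levels than the other libraries. Both tests on it were chosen after this was seen, on lists fixed before. The log2 ratios of these tests are differences of log2(CPM + 1), which shrinks them for genes near 0 CPM. Of 14 endothelial markers, 10 were highest there, with a median log2 ratio of 0.46 to the highest other library; 3 of the 14 were tested genes, present in all libraries, and 1 is in another list. KDR (42.6 CPM), VWF (26.2 CPM), MMRN1 (22.3 CPM), CDH5 (19.2 CPM) and TIE1 (6.96 CPM) were highest there, while ESAM, the most abundant, was lowest there (62.4 CPM against 69.9 to 85.1), and PECAM1, LYVE1 and ROBO4 were higher elsewhere. An interferon response shared by the resistant cells is argued against: the interferon genes had a median log2 ratio to control of -0.146 in resistant replicates 1 and 2, and of 1.16 in replicate 3. RNA or reads of another cell type may account for the endothelial genes, and a response in that culture alone stays open for the interferon genes, untested.

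The rise of ribosomal protein genes was weighed against 2 technical explanations, with tests chosen before. Gene length and GC bias as the whole cause is argued against, since the median log2FC of the 57 genes was 0.265 before and 0.317 after a trend on both was removed (bootstrap interval 0.246 to 0.387). Library-to-library variation may account for it. In mean log2 CPM the lowest resistant library lay 0.074 above the highest control library, less than the range of 0.305 among resistant libraries. That gap is not the difference between group means: the list's mean log2FC was 0.27, and the groups did not overlap. A difference between resistant and control cells stays open: the list passed camera at the preset correlation (adjusted p = 2.91e-06) but not with an estimated correlation (adjusted p = 0.75) or in fry (adjusted p = 0.092).

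Control replicate 1 had 96.7 CPM in sum over 20 trophoblast and early embryo genes, a list chosen after the data were seen, against 34.4 to 41.8 CPM in the other libraries. Over all genes, 44 stood apart in control replicate 1 and 43 in resistant replicate 3 by over 1.5 on the log2(CPM + 1) scale, against 3 to 13 in the others. Of these, 14 in control replicate 1 and 20 in resistant replicate 3 reached 10 CPM, against 0 to 1 in the others. Control replicate 1 had the fewest counts, 1913469, so few counts there make a high CPM. Among the 6 tested genes of chromosome Y, 5 were lower in resistant cells, with a median log2FC of -1.28.

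The 10 splits of the 6 libraries into 3 and 3, of which the real one is 1, are too few for a share under 0.05. The real split gave 1269 higher, 1332 lower, 175 at least doubled and 358 at least halved genes, and the highest of the other splits gave 0 of each. Each other split mixes the groups, so any strong group difference widens the spread within its sides. The 0 calls there therefore do not measure chance. For lists passing camera, the real split gave 6 and the highest other 5, with 0 genes called. The number of lists passing camera at the preset correlation was thus close in the real split and in 1 other. That other split also mixes the groups and can keep part of their difference, so its 5 lists do not measure chance either.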
